A study of Mus musculus with 28 samples.

How the data were processed

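The series covers 28 samples from mouse gonads at embryonic day 13.5, when male and female primordial germ cells (PGCs, the precursors of sperm and eggs) have colonised the gonad. Per the labels, germ cells were sorted by flow cytometry for the surface antigen SSEA1 and the negative fraction was kept as gonadal soma. The germ cells came from a cross in which Setdb1, the gene of an H3K9 methyltransferase, was deleted (KO, delta/-), with control genotypes Het1 (delta/+), Het2 (flox/-) and wild type (flox/+). Of the samples, 16 are RNA-seq libraries, 10 are ChIP-seq libraries for H3K9me3, H3K27me3 or total H3, and 2 are PBAT libraries for DNA methylation. The tables used here hold no PBAT values, and DNA methylation is not analysed here. The total H3 library, from wild-type males, has no KO partner and is not analysed here. The labels do not say whether replicates are separate embryos or pools, so the limma p-values for RNA measure the spread between libraries. Fisher's tests and permutations take genes, promoters or families as their units instead, and camera compares listed genes with other genes.

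Reads were aligned to mm9 with BWA and the RNA libraries were also handled with SAMtools, per the submitters' processing notes, which name Bismark for PBAT. Their versions, the read counter, the total used for scaling and the treatment of reads from repeats with many copies are not given in the sources used here. Per the file headers, all RNA and ChIP values are RPKM (reads per kilobase, scaled to library size), made by the authors and not rescaled here. The deposited gene table gives 1 RPKM per Ensembl gene. The deposited promoter table gives the RPKM of each mark within 1 kb of either side of the Ensembl transcription start. The third deposited table gives RPKM pooled over all copies of each of 539 repeat families, with the number of genomic elements per family (other unit, a plain count) and a mappability from 0 to 1 (a fraction, computed by the authors in a way that is not stated). Neither of these last columns was used. Names came from the files; 20551 of 22138 gene identifiers were also found in the reference names, and 39 of 55 blank or numeric names were replaced from them. The reference annotation is of another build, so no coordinates are given.

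The fixed design used 12 RNA libraries in one fit of 4 group means, with Het1 and Het2 pooled as Het: male Het (n = 4), male KO (n = 2), female Het (n = 4) and female KO (n = 2). Values were taken as log2(RPKM + 1), and features at RPKM 1 or more in at least 2 libraries were tested with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3. Tests were two-sided, with a Benjamini-Hochberg adjusted p threshold of 0.05 across all features of a contrast. The contrasts were KO minus Het in males, in females and averaged over the sexes, the female minus male difference of these effects, female minus male in Het, and Het1 minus Het2 in a fit of 6 groups. This left 13518 genes and, because repeat RPKMs are low, only 12 of the repeat families. A repeat fit with a filter at RPKM 0.1 and a pseudocount of 0.1, testing 528 families, was added after the values were seen. Wild-type libraries (1 per sex) stayed outside the fits.

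Gene lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry; p-values were adjusted over 23 lists. They cover germ cell programmes (pluripotency, germline genes kept silent in soma by DNA methylation, meiosis, male fate, oocyte, piRNA), chromatin (H3K9 methylation, DNA methylation, Polycomb, Hox and developmental regulators, imprinted genes), states (p53 and apoptosis, interferon, 2-cell stage, proliferation, Y-linked) and other gonadal cells (Sertoli, Leydig, pregranulosa, stromal, endothelial, macrophage, erythroid). Repeat families were grouped by name into IAP, ETn/MusD, MMERVK10C with RLTR10, GLn, VL30, MLV, MERVL with MT2, MaLR, LINE-1 and SINE. The MLV pattern also takes in families RLTR40 to RLTR47. No family matched the planned MMERVK9 and satellite groups.

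Each mark has 1 ChIP library per sex and genotype. A feature was therefore called by a rule of size with no p: a 2-fold difference between KO and Het in the same direction in both sexes, after a pseudocount of 0.1, at RPKM 0.5 or more for repeats and 1 or more for promoters in both sexes. Beside it stands limma over the 4 libraries with sex as a term, whose only error is the difference between the sexes. Genes raised in KO were compared with genes losing promoter H3K9me3 by Fisher's exact test, and effects on repeat RNA and repeat H3K9me3 were compared by correlation across families with permutation p-values. Medians were placed among 10000 random lists matched on expression in 20 bins, or on mark level. Soma and PGC, with 1 C57BL/6 library each, were compared by such percentiles. The planned comparison of H3K9me3 between soma and PGC at repeats could not be made because the repeat table lacks the soma library, and it was made at promoters instead.

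The deposited values hold no read counts, so the depth of the RNA libraries is unknown and no counting interval is given. RPKM sums over genes ran from 295821 to 345131, and between 4767 genes (male KO replicate 1) and 7024 genes (female Het2 replicate 1) were listed at 0. In the promoter table the most frequent low value, taken as 1 read, is 0.025, 0.024, 0.023 and 0.019 RPKM for H3K9me3 (male Het, male KO, female Het, female KO), and 0.017, 0.019, 0.018 and 0.018 RPKM for H3K27me3. In the repeat table male replicate 1 libraries carry 2 decimals and male replicate 2 libraries and the male wild type carry 3, so male values were also compared within each replicate number. The fits were tested on simulated data. With all 13518 genes run, changes of 1 log2 unit were recovered in 56% (male), 58% (female) and 82% (both sexes) of the genes altered, and changes of 2 units in 92%, 89% and 99%; of the calls 5.7%, 5.2% and 9% were false, all above the 5% aimed at. With 528 repeat families run, 85.2%, 84.1% and 96.6% were recovered at 1 unit, and 98.9%, 100% and 100% at 2 units, with 3%, 4.7% and 2.8% of the calls false. For ChIP, simulated falls of 1.5 and 2.5 log2 units were recovered by the rule of size in 87.5% and 93.3% at repeats for H3K9me3 (95 run), 100% and 90.9% for H3K27me3 (66 run), 84.8% and 96.9% at promoters for H3K9me3 (195 run), and 97% and 92% for H3K27me3 (1667 run), with 0 unaltered features called.

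Design, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Genes are named as follows: Setdb1; per KO contrast and direction up to 10 genes with the largest log2 change among those that pass and whose KO libraries all lie beyond all Het libraries of the same sex, or the 3 with the smallest p where fewer than 3 pass; up to 4 members per gene list or repeat group; up to 5 per direction for female against male; and up to 10 promoters per direction. Predicted gene models are named only after named genes. 1 gene that the rule names is not reported here. Items outside the rule, among them Dazl in a plot, were chosen after their values were seen. The alternatives were other pseudocounts, filters and scalings, 1 control genotype at a time, wild type added, replicate number as a block, eBayes without trend, and leaving out each library; other splits of the libraries were refitted, 100 drawn where more exist. Splits with 1 library per sex and replicate number in the smaller group, and a term for the split with the most calls, were added after the results were seen. Plots and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.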

Results

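The germ cell libraries were first compared as they stand. Library depth for RNA is unknown, and the 12 libraries of the cross had mean rank correlations of 0.961 to 0.971 with the others of their sex, lowest in male Het1 replicate 1 and female Het2 replicate 1. The first principal component, with 52.2% of the variance, parted the sexes, and the second, with 14.5%, had male Het1 replicate 1, female Het2 replicate 1 and both KO replicates numbered 1 at its positive end. Setdb1 RNA itself was lower in KO than in every Het library of the same sex: 29.2 ± 2.89 RPKM (SD, n = 2) against 46.1 ± 6.25 (n = 4) in males, and 33.0 ± 2.38 (n = 2) against 45.7 ± 9.05 (n = 4) in females. The log2 difference over both sexes was -0.54 (SE 0.13, adjusted p = 0.0783 by limma), which does not pass the threshold. The wild-type libraries stood at 55.43 (male) and 45.3 RPKM (female).

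In male PGCs, where the comparison asks what the loss of Setdb1 does to the transcriptome, 83 genes rose and 0 fell. Alox15, which encodes a lipoxygenase, went from 0.76 ± 0.629 RPKM in Het (n = 4) to 32.2 ± 6.31 in KO (n = 2), a log2 difference of 4.28 (SE 0.29, adjusted p = 1.3e-05 by limma). The steroid enzyme genes Cyp17a1 (0.29 to 10.96 RPKM, log2 difference 3.23) and Cyp11a1 (0.113 to 8.35 RPKM, 2.90) rose as well. So did the deubiquitinase gene Dub3 (0.118 to 13.4 RPKM, adjusted p = 1.72e-04), the lectin-like gene Clec2g (0.415 to 12.8 RPKM, 3.40), Cyp2b23 (0.968 to 20.6 RPKM, 3.30), Cml2 (1.13 to 13.8 RPKM, 2.80) and Gabrr1, a GABA receptor subunit gene (0.0325 to 5.61 RPKM, 2.67). Klk1b24 and Zscan4d were listed at 0 in all 4 male Het libraries and stood at 6.70 and 6.36 RPKM in KO. The predicted gene 2010005H15Rik, picked after its values were seen, had the highest difference, from 0.12 to 63.6 RPKM.

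Among the lists, 2-cell stage genes and steroidogenic Leydig cell markers stood out in males. Of 20 listed 2-cell genes 7 were tested, and 4 rose (4 adjusted over the list alone). All 4 are copies of Zscan4, a gene active in early embryos. The filter counts KO libraries too and so favours listed genes raised in KO. Hence 4 of 7 is not the share of the list that rose. The list passed by camera (adjusted p = 6.82e-10, and adjusted p = 0.0207 with an estimated correlation). Of 8 steroidogenic genes, 5 rose (6 adjusted over the list alone), among them Cyp17a1, Cyp11a1, Hsd3b1 (0.248 to 6.21 RPKM) and the renin gene Ren1 (0.122 to 6.46 RPKM). Camera gave an adjusted p of 1.03e-17, and adjusted p = 0.0136 with an estimated correlation. These steroidogenic genes are abundant in the soma library (Cyp17a1 176.62 RPKM, Insl3 191.91 RPKM), and the male wild-type library had 2.8 RPKM of Cyp17a1. Further lists passed camera at the preset correlation but not with an estimated one (the Y-linked list also passed by fry, adjusted p = 0.0331). With an estimated correlation their adjusted p-values were 0.739 (germline genes silenced by DNA methylation), 0.329 (imprinted), 0.739 (stromal), 0.874 (pluripotency), 0.374 (Polycomb) and 0.269 (Y-linked).

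All 83 genes had both male KO libraries above all 4 Het libraries; chance gives this order in 6.67% of genes not chosen for a difference, so it is no further test of these. Beside the 0 falling genes by limma stand 615 genes at an unadjusted p under 0.05 in either direction. The falls with the smallest p were in Cox6b2 (32.4 to 17.5 RPKM, adjusted p = 0.0931), Upk2 (adjusted p = 0.126) and Sirt4 (adjusted p = 0.168). Several of the raised genes (Zscan4, Dub3, Klk1b24, Clec2g, Cyp2b23, Cml2) belong to families of similar genes, and how reads shared between such genes were counted is not given. Within replicate number 1 and within number 2, the log2 differences were 4.26 and 4.31 for Alox15, 3.64 and 2.82 for Cyp17a1, 3.36 and 2.17 for Zscan4d and -0.78 and -0.49 for Setdb1. The number of genes fell to 29 without male KO replicate 1, to 36 without male KO replicate 2, and to 53 or 52 with Het2 or Het1 alone as controls.

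**Figure D1:**
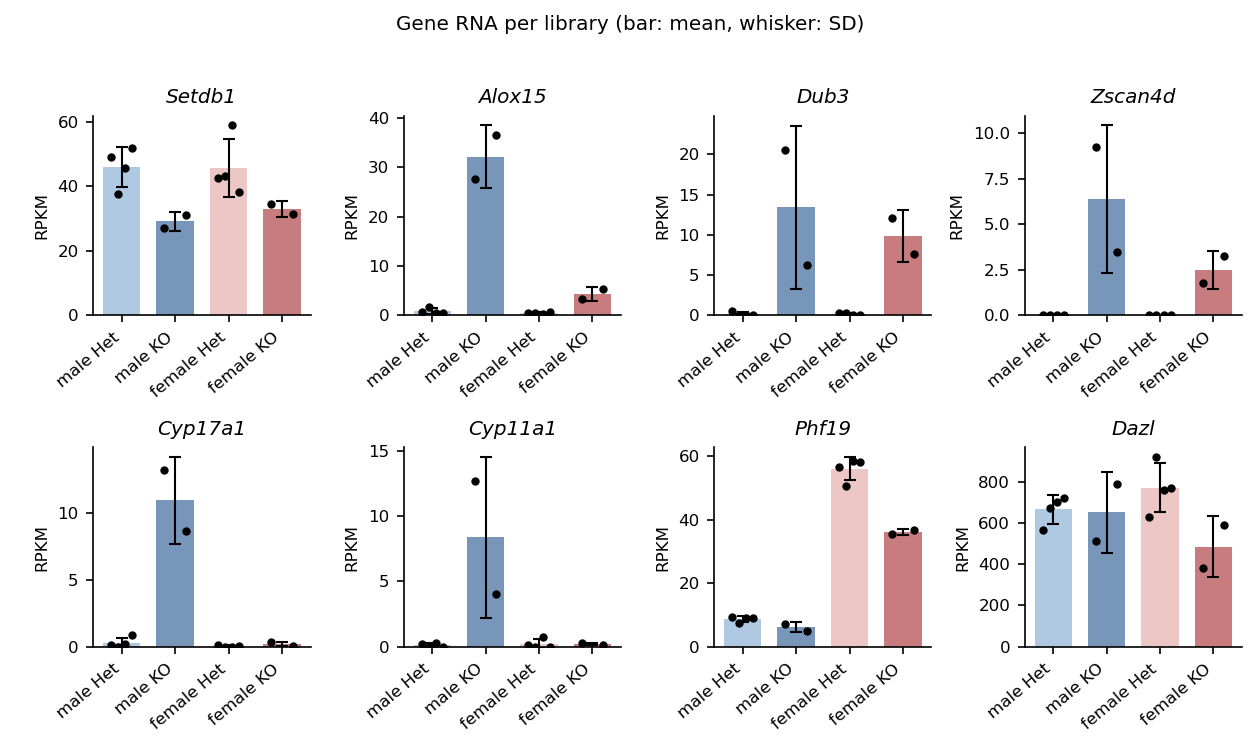
RNA level (RPKM, linear axes from 0) of 8 genes in male and female Het (n = 4 each) and KO (n = 2 each) germ cells; points are libraries, bars means and whiskers SDs. Setdb1 is lower in all KO libraries, Cyp17a1 and Cyp11a1 are higher in male KO than in male Het, and Dazl, shown as an abundant germ cell gene, overlaps between the groups in males.

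In female PGCs 54 genes rose and 1, the predicted gene Gm17485, fell. Gabrr1 went from 0.198 ± 0.249 RPKM in Het (n = 4) to 22.3 ± 5.44 in KO (n = 2), a log2 difference of 4.28 (SE 0.23, adjusted p = 1.46e-06 by limma). Dub3 (0.12 to 9.84 RPKM, log2 difference 3.25), Trim52 (1.85 to 12.6 RPKM, 2.30), the hair follicle protein gene Tchh (2.47 to 13.9 RPKM, 2.30), Clec2g (0.085 to 3.95 RPKM, 2.17), the DEAD-box helicase gene D1Pas1 (5.15 to 22.2 RPKM, 2.05), the dynein gene Dnahc6 (0.0825 to 3.02 RPKM, 1.89) and Alox15 (0.423 to 4.21 RPKM, 1.85) also rose. The complement gene C6 and the receptor gene Pilrb2 were listed at 0 in all female Het libraries and stood at 2.73 and 2.70 RPKM in KO. All 54 had both KO libraries above all Het libraries. The falls of named genes with the smallest p did not pass: Cubn, the cubilin endocytic receptor gene (7.995 to 3.55 RPKM, adjusted p = 0.0607), Elavl2 (adjusted p = 0.0981) and Chrm4 (adjusted p = 0.115). One 2-cell gene, Zscan4d, rose (4 adjusted over the list alone), and 0 of 8 steroidogenic genes did (0 adjusted over the list alone); 1670 genes had an unadjusted p under 0.05 in limma. The lists that passed camera at the preset correlation (2-cell, pluripotency and proliferation genes) each had adjusted p = 0.972 with an estimated correlation. The female count rests on single libraries: it was 3 without female KO replicate 1, 5 without female KO replicate 2 and 164 (140 higher, 24 lower) without female Het2 replicate 1. It also changed with scaling, to 23 by median centring and 12 by quantile normalization, and was 145 with replicate number as a block.

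Over both sexes 137 genes rose and 4 fell, of 13518 tested. Gabrr1 (log2 difference 3.48, SE 0.16, adjusted p = 1.33e-07 by limma), Dub3 (3.37), Alox15 (3.07), Clec2g (2.79), Cyp2b23 (2.36), Cml2 (2.26) and Efhc2 (2.13; 2.08 to 12.6 RPKM in males and 3.88 to 16.7 in females) rose most among genes whose KO libraries lie apart in both sexes. This order held for 115 of the 137 and 3 of the 4 (0.44% by chance in genes not chosen for a difference). Among the falling genes, Phf19, a Polycomb accessory factor gene, went from 56.1 ± 3.69 to 36.2 ± 0.941 RPKM in females and from 8.65 ± 0.853 to 6.13 ± 1.57 in males (log2 difference -0.53, adjusted p = 0.0386). The intermediate filament gene Ina (-0.59, adjusted p = 0.0279) and Rhpn2 (-0.50, adjusted p = 0.0145) also fell in all KO libraries, and Gm17485 was the remaining gene. The male and female responses shared 25 raised genes where 0.332 would be shared if the calls were independent (Fisher's exact p = 1.37e-42). They are not quite so, since both contrasts use the same estimate of spread per gene and similar genes count separately. Of the 83 male genes 75, and of the 54 female genes 50, had positive differences in the other sex. Across all genes, which are not independent replicates, the male and female log2 differences had a Pearson r of 0.414 and a Spearman rho of 0.343.

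**Figure D2:**
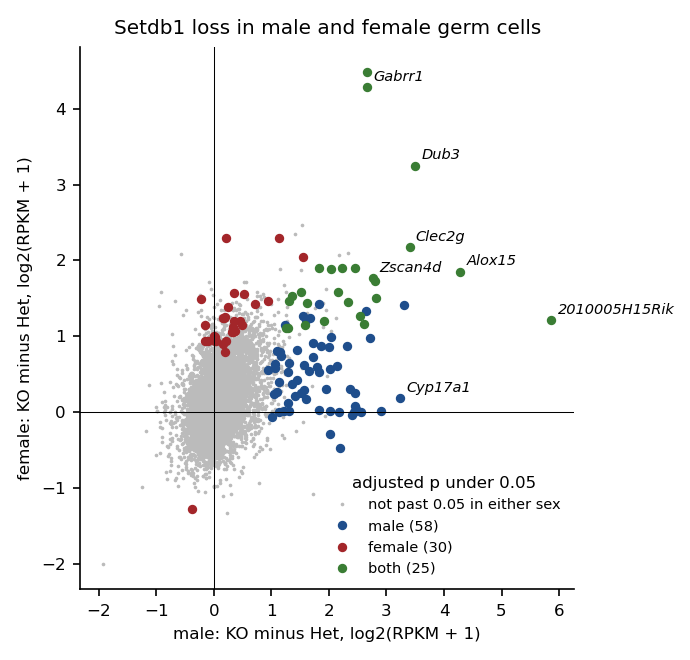
Log2 difference of KO from Het, on log2(RPKM + 1), in males (horizontal) and females (vertical) for each gene tested, coloured by the sex in which the adjusted p was under 0.05. 25 genes pass in both sexes, 58 in males alone and 30 in females alone, which does not by itself show a difference between the sexes.

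The fixed lists show which programmes moved over both sexes. Among the 7 tested of 20 listed 2-cell genes, Zscan4d, Zscan4c, Zscan4e and Zscan4b rose (4 adjusted over the list alone). Their adjusted p-values were 4.4e-05, 0.0081, 0.0023 and 0.0021 by limma, in this order. The list gave an adjusted p of 7.34e-06 by camera, adjusted p = 0.139 with an estimated correlation, and 9.42e-04 by fry. The steroidogenic list had 4 of 8 raised (5 adjusted over the list alone), through the males, with adjusted p = 0.139 with an estimated correlation. Of 21 pluripotency and PGC genes, 0 rose and 0 fell (1 fell adjusted over the list alone), Alpl having the lowest log2 difference of -1.11 (adjusted p = 0.0802). Camera placed the list lower (adjusted p = 4.58e-05), with adjusted p = 0.628 with an estimated correlation. One of 21 germline genes silenced by DNA methylation in soma, Tex13, rose (1.33, adjusted p = 0.012; 2 adjusted over the list alone). Tuba3b stood at 1.46 (adjusted p = 0.0714), Taf7l at 1.79 (0.283) and Tex101 at 1.26 (0.476). Of 17 Polycomb genes Phf19 alone fell (1 adjusted over the list alone; adjusted p = 0.512 with an estimated correlation for the list). Imprinted genes had 0 of 20 passing and 4 raised adjusted over the list alone, with Dlk1 at 1.17, Nnat at 0.85 and Igf2 at 0.74 (adjusted p = 0.0377 by camera, higher, and adjusted p = 0.628 with an estimated correlation). The imprinted list is also far higher in soma (median log2 ratio of PGC over soma -2.55). Stromal markers had a positive median in the same contrast (0.489), so a share of soma was not separated from this rise.

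In the remaining lists 0 genes passed by limma over both sexes. Adjusted over the list alone, 5 Hox and developmental regulators rose and 1 fell, with Hoxa5 at 0.88 (adjusted p over all genes 0.0856). By the same measure 2 DNA methylation genes (Tet3 0.66 and Dnmt3b 0.52), 1 H3K9 cofactor gene (Atf7ip, 0.56), 2 stromal genes (Nr2f2 0.93 and Pdgfra 0.88) and 1 endothelial gene (Kdr, 0.92) rose, and Setdb1 fell. The stromal list was higher too by camera (adjusted p = 0.0259), with adjusted p = 0.666 with an estimated correlation. Tet3, Kdr, Nr2f2 and Pdgfra, and the Hox list by its median, have more RNA in C57BL/6 soma than in PGCs. A share of soma was not separated from their rises. Proliferation genes passed camera with lower values and 0 single genes (adjusted p = 0.666 with an estimated correlation). Meiosis genes (Tex15 0.94, adjusted p = 0.224), male fate genes (Tdrd9 1.02, 0.247), oocyte genes (Ooep -0.39, 0.615), piRNA genes (Gtsf1 1.56, 0.215), p53 and apoptosis genes, the 9 measured interferon genes (Oasl2 0.35, 0.6247), Y-linked genes (Kdm5d 0.32, 0.381), Sertoli (Fgf9 0.99, 0.206), pregranulosa (Lgr5 0.60, 0.234), macrophage (C1qb 0.38, 0.814) and erythroid markers (Hbb-b1 0.74, 0.897) gave 0 genes also over the list alone. By limma 1708 of all genes had an unadjusted p under 0.05. The count of 141 genes over both sexes fell to 65 and 83 without female KO replicates 1 and 2, to 53 and 57 without male KO replicates 1 and 2, and to 67 or 55 with Het2 or Het1 alone, and it rose to 256 without female Het2 replicate 1. With replicate number as a block it was 297.

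The difference of KO from Het was not the same in the sexes for 7 genes, all with higher values in males. For Cyp17a1, carry-over of steroidogenic somatic cells into the male KO libraries stays a candidate source, as weighed below. Cyp17a1 differed by -3.04 log2 units (female minus male, adjusted p = 0.00451 by limma), the lipoxygenase gene Alox12e by -2.004 (adjusted p = 0.0105; 0.51 to 5.16 RPKM in males), the matrix metalloproteinase gene Mmp10 by -2.21 (adjusted p = 0.0305; 0.0425 to 4.88 RPKM in males) and 2010005H15Rik by -4.66 (adjusted p = 3.39e-05). Usp9y, which lies on the Y chromosome and cannot respond in females, went from 0.425 to 7.38 RPKM in males. The predicted genes Gm10256 and Gm3376 stood at 4.46 and 3.54 RPKM in male KO. Both are listed at 0 in female RNA and at their promoters in the female ChIP libraries for H3K9me3 and H3K27me3, as is the promoter of Usp9y, and females show no trace of them in these tables, so a difference between the sexes cannot be read from them. The promoter of Gm10256 is near 0 in males too. Alox15 and Cyp11a1 had adjusted p = 0.0648 each. The count was 0 with a pseudocount of 0.1, 13 with median centring, and 64 (17 higher, 47 lower) without the filter on low values.

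Endogenous retroviruses are known targets of H3K9 methylation, and in KO germ cells of both sexes the RNA of some of their families rose, mainly IAP, MMERVK10C and GLn. IAPLTR1_Mm, the long terminal repeat of IAP elements, went from 0.588 ± 0.231 RPKM in male Het (n = 4) to 3.82 ± 0.708 in male KO (n = 2), and from 0.39 ± 0.131 to 5.73 ± 3.25 in females, a log2 difference over both sexes of 1.90 (SE 0.16, adjusted p = 3.39e-07 by limma). The internal region IAPEz-int rose from 0.315 to 2.77 RPKM in males and from 0.24 to 4.22 in females (1.74), MMERVK10C-int from 0.105 to 1.98 and from 0.138 to 2.03 (1.32), and MMERGLN-int from 0.735 to 1.95 and from 0.598 to 1.77 (0.78). Within a sex the size of some rises rested on 1 KO library. MMERVK10C-int went from 1.29 to 0.64 without male KO replicate 1, and from 1.35 to 0.91 without female KO replicate 2. MMERGLN-int went from 0.75 to 0.41 without male KO replicate 2, and from 0.81 to 0.69 without female KO replicate 2. RLTR4_Mm, of the MLV group, passed over both sexes (0.36, adjusted p = 0.0102) but in neither sex, and its male groups overlap. Of the 12 families tested, 4 rose in males, 4 in females and 5 over both; 0 fell, and 5 had an unadjusted p under 0.05 in each contrast. The tested ETn family MMETn-int (0.53, adjusted p = 0.385), MMVL30-int (0.20), the SINEs PB1 (0.05) and PB1D9 (0.01), and AluF_3 (-0.06) did not pass. With so few families, median centring and quantile normalization move the median itself, from 0.281 over both sexes to -0.09 and -0.397. Under median centring 4 families were called higher and 5 lower in males, 3 and 5 in females and 4 and 5 over both, and RLTR4_Mm turned to -0.01.

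With the low filter, chosen after the values were seen, 36 of 528 families rose and 0 fell over both sexes (74 at an unadjusted p under 0.05), 13 in males and 10 in females. They included 11 of 15 IAP families (15 adjusted over the group alone), 7 of 9 MMERVK10C and RLTR10 families (8 alone), 3 of 3 GLn families (3 alone), 2 of 5 ETn/MusD families (5 alone; ETnERV-int 0.97 and ETnERV2-int 0.92), 5 of 17 MLV families (8 alone), 1 of 3 VL30 families (2 alone), and MERVL-int, 1 of 7 MERVL and MT2 families (0.71, adjusted p = 0.0244; 1 alone). By camera, IAP had adjusted p = 0.00841 and MMERVK10C 0.0126 with an estimated correlation, GLn 0.052, ETn/MusD 0.254, VL30 0.254, MLV 0.504 and MERVL 0.9. LINE-1 elements had 2 of 102 families raised (L1Md_Gf 0.60 and L1Md_A 0.50; 0 alone), and 0 of 92 MaLR and 0 of 27 SINE families passed (0 alone in each). The shared order of both KO libraries above all Het libraries in both sexes held for 27 of the 36. It did not hold for ETnERV-int and ETnERV2-int, where male KO replicate 1 lay within the male Het range (0.27 in 0.25 to 0.419 RPKM, and 0.18 in 0.13 to 0.287). Their male rise came from male KO replicate 2 (1.5 and 0.966 RPKM). In males, within replicate numbers 1 and 2, the log2 differences were 2.42 and 3.19 for IAPEz-int, 2.27 and 2.84 for IAPLTR1_Mm, 3.99 and 2.04 for MMERVK10C-int, 1.33 and 1.28 for MMERGLN-int, 1.22 and 0.25 for RLTR4_Mm and -0.55 and 1.24 for MMETn-int. No difference of the effect between the sexes passed for any family by limma (0 of 12 with 0 at an unadjusted p under 0.05, and 0 of 528 with 3). With 2 KO libraries per sex this does not show equal effects. With the low filter the median effect over all families was 0.293 in males and 0.047 in females, a shift that was not tested. Of the raised families 9 were shared by the sexes (0.246 if the calls were independent, Fisher's exact p = 8.65e-16). As for genes, both contrasts use the same estimate of spread per family, so they are not. With median centring 18 families passed over both sexes, 4 in males and 8 in females. With replicate number as a block 70 passed over both sexes.

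**Figure D3:**
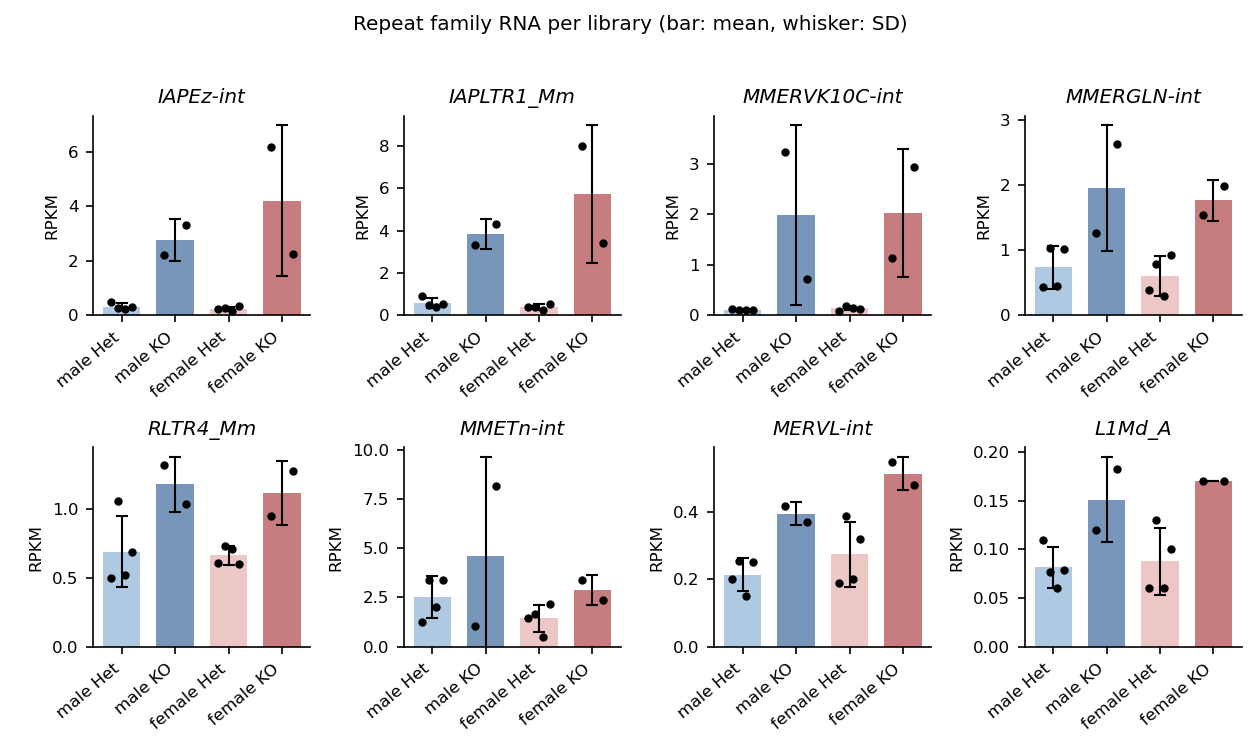
RNA level (RPKM, linear axes from 0) of 8 repeat families in male and female Het (n = 4 each) and KO (n = 2 each) germ cells; points are libraries, bars means and whiskers SDs. IAPEz-int, IAPLTR1_Mm and MMERVK10C-int are higher in every KO library than in every Het library, whereas MMETn-int overlaps in males.

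H3K9me3 and H3K27me3 at repeats address whether the marks left these elements in KO. At the 102 families with enough H3K9me3, 0 lost or gained 2-fold in both sexes, but 89 were lower in KO in both sexes and 5 higher. IAP families carried a median of 2.03 RPKM of H3K9me3 in male Het and 1.70 in female Het, and the median log2 differences were -0.18 and -0.36, with 16 of 16 lower in both sexes; those of ETn/MusD families were -0.48 and -0.43, with 5 of 5 lower. MMERVK10C with RLTR10 (9 of 9), GLn (3 of 3), MLV (12 of 13), VL30 (2 of 3) and LINE-1 families (3 of 6) were lower in both sexes too, whereas both tested MERVL and MT2 families and 1 of 2 MaLR families were higher. H3K27me3 was lower at 65 of 66 families in both sexes, again with 0 past 2-fold, and IAP medians were -0.35 and -0.22. Limma over the 4 libraries, with 1 residual degree of freedom, called 21 families lower and 0 higher for H3K9me3 (46 at an unadjusted p under 0.05), and 48 lower and 0 higher for H3K27me3 (51). Families whose RNA rose had lost no more H3K9me3 than random lists of similar mark level: -0.18 against -0.18 in males and -0.35 against -0.39 in females. These lists were drawn from all 99 families with both measures, the 35 raised ones included, which draws the medians together. The other families alone, not matched on level, had medians of -0.18 in males and -0.31 in females.

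**Figure D4:**
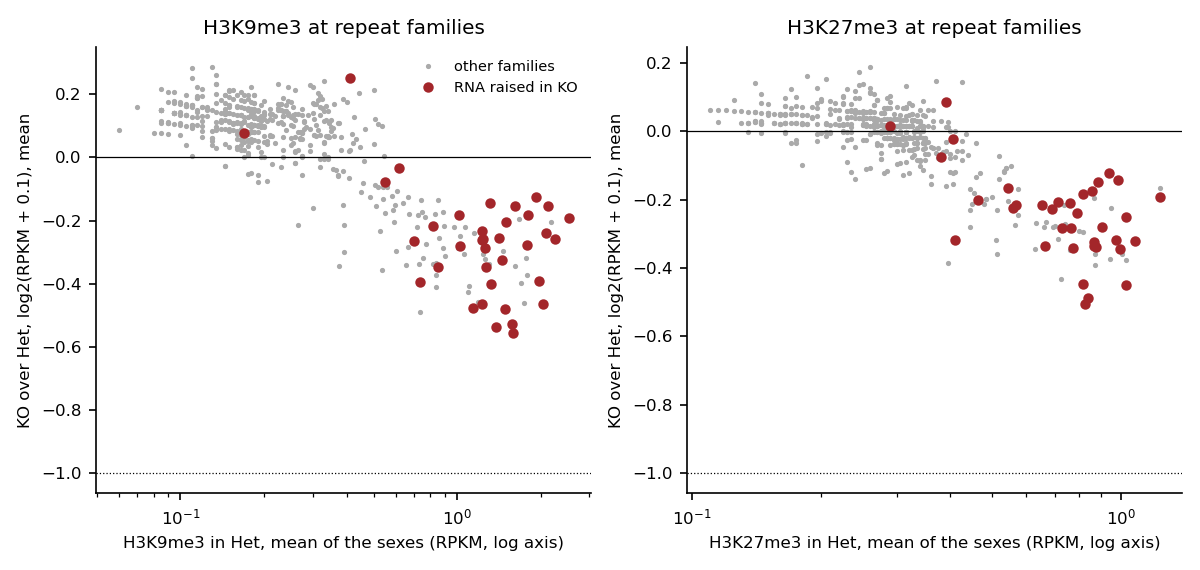
Mark level in Het (RPKM, log axis) against the log2 difference of KO from Het with a pseudocount of 0.1, both as means of the sexes, for H3K9me3 (left) and H3K27me3 (right) at repeat families; red points are families whose RNA rose in KO with the low filter. Families with high levels of either mark lie below 0, red or not, and none reaches the dotted line of a 2-fold loss.

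Promoters gave larger single changes. Of 216 promoters with enough H3K9me3, 17 lost 2-fold or more in both sexes and 1 gained. The promoter of Cd59a, a complement regulator gene, went from 1.69 to 0.276 RPKM in males and from 1.56 to 0.23 in females. Those of Zfyve27 (log2 differences -1.87 and -1.70), Mfap2 (1.33 to 0.327 RPKM and 1.10 to 0.324 RPKM), the chemokine gene Cxcl1 (-1.47 and -1.74), Pilra (-1.56 and -1.42), H2-T24 (-1.35 and -1.28), Chst5 (-1.28 and -1.19), Abp1 (-1.30 and -1.16), Strc (-1.25 and -1.12) and Endou (-1.40 and -1.11) lost it too. Oog3, an oocyte gene, gained. It was listed at 0 in male Het and stood at 1.19 RPKM in male KO, and went from 0.15 to 1.15 in females. RNA did not pass at those of these genes that were tested: Cd59a had a log2 difference of 1.03 (adjusted p = 0.132 by limma), Mfap2 1.20 (0.0912) and Abp1 0.93 (0.0631). Cxcl1, Chst5, Strc, Endou and Oog3 were not among the genes tested for RNA. Limma over the 4 libraries called 39 promoters lower and 2 higher. After median centring 8 were lower and 2 higher by the rule of size, and with a pseudocount of 1 there was 1. For H3K27me3, of 1751 promoters 0 gained and 1 lost 2-fold, Pla2g2c (1.45 to 0.657 and 1.24 to 0.447 RPKM); limma called 0 (173 at an unadjusted p under 0.05).

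The promoter and RNA changes were then joined. Of 41 genes measured in both tables, 3 rose in RNA and 8 lost promoter H3K9me3, and 0 did both (Fisher's exact p = 1, two-sided), a comparison too small to exclude an overlap. Across the 7 families with both measures, the RNA and H3K9me3 effects had a Spearman rho of -0.04 (exact p = 0.963) and a Pearson r of 0.07 (exact p = 0.872). With the low filter, across 99 families, rho was -0.38 (permutation p = 0.00019) and r -0.26 (permutation p = 0.0123). With the H3K9me3 level in Het taken out, this rho was -0.203 (permutation p = 0.0502), with -0.249 in males and -0.082 in females. Against H3K27me3 across 65 families rho was -0.26 (permutation p = 0.036) and r -0.22 (permutation p = 0.0747). Families are not independent replicates.

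The female and male Het germ cells differ by sex as such. Stra8, which starts meiosis in the fetal ovary, stood at 0.678 RPKM in male Het and 164 in female Het (n = 4 each), a log2 difference of 6.59 (adjusted p = 5.53e-07 by limma). Phlda2 (6.11), Cdx2 (4.75), Gata2 (4.35) and Sct (4.30) were also higher in females, and the Nodal antagonist genes Lefty2 (139 to 0.168 RPKM, -6.86) and Lefty1 (-5.89), the Y-linked genes Ube1y1 (-5.73) and Eif2s3y (-5.60) and the apoptosis gene Pmaip1 (-5.50) were lower. In all, 2373 genes were higher and 1939 lower in females; the split turned to 1955 and 2407 by median centring. Of 23 meiosis genes 18 were higher (20 adjusted over the list alone), for instance Tex15 (1.43) and Syce3 (1.30), with an adjusted p of 1.86e-08 by camera, adjusted p = 0.896 with an estimated correlation, and 0.00549 by fry. Of 13 male fate genes 7 were lower and 2 higher (7 and 2 adjusted over the list alone), with Nanos2 at -3.04 (17.6 RPKM in males, listed at 0 in females) and Tex101 at 2.98 (adjusted p = 0.135 with an estimated correlation). The male mean of Nanos2 rests on Het1 replicate 1, at 57.6 RPKM against 1.59 to 9.05 in the other male Het libraries, and without it the log2 difference was -2.09 (adjusted p = 0.0175). Of 21 pluripotency genes 9 were lower and 2 higher (11 and 3 alone; adjusted p = 0.925 with an estimated correlation), and of 9 oocyte genes 2 were higher and 2 lower (3 and 2 alone), Ooep standing at -2.31. All 4 measured Y-linked genes were lower (4 adjusted over the list alone; adjusted p = 0.0179 with an estimated correlation). Among repeats limma gave 0 differences (0 of 12 at an unadjusted p under 0.05, and 18 of 528).

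The pooling of the control genotypes was tested by comparing Het1 with Het2. The predicted genes Gm10036 (log2 difference 3.31, adjusted p = 0.00431 by limma) and Gm13225 (3.59, adjusted p = 0.00956) were higher in Het1, 0 genes were lower, and 164 had an unadjusted p under 0.05.

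Sorted PGCs and soma of C57BL/6 males, with 1 library each, show how far the sort parted the cells. Median log2 ratios of PGC over soma were 5.64 for pluripotency genes (Dppa5a 518.34 against 1.89 RPKM), 4.61 for germline genes (Dazl 607.28 against 1.89), 4.05 for piRNA genes, 3.24 for oocyte genes, 2.98 for male fate genes and 2.19 for meiosis genes, each at or above the 99.97th percentile of matched random lists. Stromal (-6.16; Col3a1 1.97 against 590.46 RPKM), steroidogenic (-5.13), Sertoli (-3.79), pregranulosa (-2.22), macrophage (-1.91), endothelial (-1.32) and erythroid markers (-7.96; Hbb-y 1.2 against 1082.43 RPKM) were higher in soma, all at or below the 7.26th percentile. Imprinted genes (-2.55, percentile 0) and Hox and developmental regulators (-2.14, 0.02nd percentile) were higher in soma as well. H3K9me3 at promoters had a median of 0.721 RPKM in soma and 0.127 in male Het PGCs, and 4113 promoters reached 1 RPKM in soma against 298 in PGCs, 105 of them in both. At 2 RPKM or more it was 35 against 42. The libraries differ in genotype and there is 1 of each. A difference in the mark cannot be told from a difference in enrichment between the 2 libraries, since a flatter soma library would give such counts.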

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

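The tests of carry-over, of library structure and of enrichment and the splits within replicate number, with their bounds, were chosen after the results were seen; the other splits of the libraries and the check for single distant libraries were planned.

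Some groups of 4 Het libraries had 1 library far from the others. This was tested in 193 groups, of which 24 had such a library, where chance sets apart about 1 in 20 groups (9.7 expected). Male Het1 replicate 1 was apart from the other 3 male Het libraries for Nanos2, a male germ cell regulator (57.6 RPKM), Taf7l (20.4), Gtsf1 (11.2), Tdrd9 (7.88), D1Pas1 (5.96), the cell cycle inhibitor gene Cdkn1b (15.4), the globin gene Hbb-y (8.87) and the repeats MMVL30-int (3.19) and MMERVK10C-int (0.12), all high, and for Bub1 (78.07), which was low. Female Het2 replicate 1 was apart for Taf7l (172.48), Gtsf1 (7.31), Tdrd9 (8.78), D1Pas1 (10.29), Figla, an oocyte transcription factor gene (15.06), Tchh (6.01), Trim52 (3.17), the globin genes Hbb-b1 (179.21), Hba-a2 (74.7) and Hba-a1 (74.63) and MMVL30-int (3.3), all high, and for Phlda2 (80.14), which was low. Female Het1 replicate 1 was high for Phf1 (7.5) and the stromal marker Pdgfra (4.68).

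The effect of the loss differed between the sexes for 7 genes, all with lower effects in females: 2010005H15Rik (-4.66), Cyp17a1 (-3.04), Usp9y (-2.56), Gm10256 (-2.44), Mmp10 (-2.21), Gm3376 (-2.18) and Alox12e (-2.0). Usp9y is Y-linked, and Gm10256 and Gm3376 are, like it, listed at 0 at their promoters in the female ChIP libraries of H3K9me3 and H3K27me3, so a difference between the sexes cannot be read from these 3. For Cyp17a1, carry-over of steroidogenic cells is weighed below as a candidate source. The male wild-type library, which is in no fit, was above all 4 male Het libraries for the steroidogenic genes Cyp17a1 (2.8 RPKM), Hsd3b1 (3.89), Star (3.89) and Cyp11a1 (3.02).

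Chance was examined by refitting other splits of the libraries with as many per group and sex. For genes over both sexes 2 of 100 splits gave as many calls, the real one (141) included; for the 12 repeat families 1 of 100 did (5, against at most 4 elsewhere), and with the low filter 3 of 100 (36, against at most 476). These splits take the libraries as interchangeable, although some share a structure. Among the 81 splits that put 1 library per sex and replicate number in the smaller group, only the real split gave as many for genes (1 of 81; at most 15 elsewhere), for the 12 families (1 of 81; at most 2) and with the low filter (1 of 81; at most 9). Each share is under 0.05, so the real split stood out among those drawn. Chance is not excluded by this, since the 81 splits, and for the 36 families also the filter, were chosen after the results were seen. For female against male in Het 1 of 35 splits gave as many (4312, against at most 2). For Het1 against Het2 it was 1 of 18 (2, against at most 0), and these splits are too few for a share under 0.05.

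The first pattern weighed is that another split called 1581 genes, several times the 141 of the real one, which points to a structure of the libraries. It puts male Het1, male KO, female Het2 and female KO, all of replicate number 1, against the rest; the 476 repeat families came from setting the 4 Het libraries of replicate 1 apart. Replicate number covers this only in part, since male Het2 and female Het1 of replicate 1 lie with the rest. Against this structure as the whole cause of the KO calls, 135 of the 141 genes also passed with a term for this split added to the fit, which called 177. What the structure is stays open, since the labels name no batch, and a difference in handling or in the stage of the embryos could each give it; no biological explanation was tested.

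The second pattern is the rise of steroidogenic genes in male KO. Carry-over of gonadal soma in general is argued against, since the stromal markers would need a median share of 0.68% of the soma level, against 4.98% for the lowest of the 5 steroidogenic genes called, and the most abundant in soma, Col3a1 (590.46 RPKM), Dcn (243.8) and Col1a1 (236.47), need 0.38%, 0.31% and -0.17%. Of the stromal list only Wt1 (5.87%) lies above 4.98%, and Nr2f2 follows at 2.37%. The 5 macrophage markers go the other way, with a median of 4.47%, but they reach at most 10.76 RPKM in soma, and their median was 13.28% in replicate 1 and -6.09% in replicate 2, so a few such cells in replicate 1 stay open. Also, 63 of the 83 genes raised in males rose by more than their whole level in soma. Carry-over of cells like that soma library does not account for those. It is 1 C57BL/6 library of SSEA1-negative cells, so cells rare in it or missing from it are not excluded. Carry-over of steroidogenic cells alone remains a candidate source. As means of both KO libraries, Cyp17a1, Cyp11a1, Hsd3b1, Ren1 and Insl3 need similar shares, from 4.98% to 6.78% (a ratio of 1.36). Within 1 library the shares are less alike, from 7.06% (Hsd3b1) to 11.22% (Ren1) in replicate 1. In replicate 2 they run from 2.33% (Ren1) to 4.74% (Cyp17a1). Ren1 is thus highest of the 5 in replicate 1 and lowest in replicate 2, which equal carry-over does not explain. The list median was larger in replicate 1 (7.22%) than in replicate 2 (2.74%). All of these 5 genes but Ren1 (0.25 RPKM) were above the 4 male Het libraries in the male wild type. Nr5a1 (0.80%) and Fdx1 (1.25%) need less. The sort for SSEA1 is meant to remove such cells. Yet the sorted C57BL/6 PGC library, outside the cross, lay above the highest male Het library for Cyp17a1 (2.07 against 0.87 RPKM) and Cyp11a1 (2.26 against 0.28). The same held for Hsd3b1 (2.44 against 0.5) and Ren1 (0.85 against 0.26), but not for Insl3 (2.39 against 2.54). Loss of Setdb1 within the germ cells stays open too, because 0 of the 5 genes had promoter H3K9me3 at 1 RPKM or more in male Het, which excludes no indirect effect.

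The third pattern is the lower H3K9me3 in KO. At repeats, families with raised RNA stood at the 63.81st percentile of lists with similar mark level in males and the 96.67th in females. For H3K27me3 they stood at the 86.57th and 99.99th. A high percentile is a smaller loss, so the raised families lost no more than these lists. The lists were drawn from all tested families, which draws the medians together. The raised families made up 35 of 99 for H3K9me3 and 30 of 65 for H3K27me3. Without matching, the raised and the other families had medians of -0.18 each in males and of -0.35 and -0.31 in females, and over 99 families a larger rise in RNA went with a larger loss (Spearman rho -0.381, permutation p = 0.00019; families are not independent). With the level in Het taken out, rho was -0.249 in males (permutation p = 0.0128), -0.082 in females (permutation p = 0.423) and -0.203 over both (permutation p = 0.0502). As these values disagree, a loss at the targets of Setdb1 and a lower enrichment of the whole KO libraries cannot be told apart, with 1 library per group and no spike-in named. At the 195 promoters with the mark in Het, 8 were lower by 2-fold in both sexes after median centring. Pairing the sexes at random among promoters of similar level gave a median of 2, and as many in 3 of 10000 pairings (permutation p = 4e-04). No repeat family fell by more than -0.52 in both sexes. The same promoters thus fell in both sexes more often than random pairing gave. Such pairing cannot tell a loss at targets of Setdb1 from a lower enrichment that reaches the same promoters in both sexes. The other 9 of the 17 ended under 2-fold because the centring took off -0.16 in males and -0.29 in females, so they say nothing either way.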

How the results depend on the processing

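The low-filter repeat settings (RPKM 0.1, pseudocount 0.1), alone or with the replicate block or centring, were chosen after seeing the data; the other alternatives were planned. Over 234 reported values, 4005 alternative values kept direction and side of the threshold, 211 kept direction but no longer passed, 67 newly passed and 53 reversed; of 110 values that passed, 52 stopped passing under at least 1 alternative. Unless stated, the cause of a change was not tested.

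Counts of genes that moved by more than 1.5 times were as follows. In males (83) the count was 185 with no filter (184 higher, 1 lower), 16 with a filter at RPKM 5, where fewer genes are tested, 53 with Het2 and 52 with Het1 as only controls, where fewer libraries are used. In females (55) it was 30 with a pseudocount of 0.1, 140 with no filter, 10 at RPKM 5, 23 by median centring, 12 by quantile normalization, 8 with Het2, 7 with Het1 and 145 with the replicate block. Over both sexes (141) it was 310 with no filter, 31 at RPKM 5, 67 with Het2, 55 with Het1 and 297 with the block. For the difference between the sexes (7) it was 0 with a pseudocount of 0.1, 64 with no filter, 1 at RPKM 5, 13 by median centring, 13 by quantile normalization, 2 with Het2, 13 with wild type added and 13 without the trend. Female against male (4312) had 1301 with Het2 and 1117 with Het1, and Het1 against Het2 (2) had 0 with no filter.

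Of repeat families, males (4) had 12 with no filter, 9 by median centring (4 higher, 5 lower), 7 by quantile normalization (3 higher, 4 lower), 13 with the low filter, 40 with the low filter and block, and 4 with the low filter and centring. Females (4) had 10, 8 (3 higher, 5 lower), 8 (3 higher, 5 lower), 10 and 34, and 8 with the low filter and centring. Both sexes (5) had 34, 9 (4 higher, 5 lower), 9 (4 higher, 5 lower), 36 and 70, and 18 with the low filter and centring. With 12 families of which 5 rise, both scalings subtract part of the rise by construction. A filter at RPKM 5 left too few families for a fit.

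Promoters with changed H3K9me3 (18) were 1 with a pseudocount of 1, 43 at 1.5-fold (2 higher, 41 lower), 0 at 3 times the minimum, where 25 are tested, and 10 by median centring (2 higher, 8 lower). For H3K27me3 (1) they were 0 with a pseudocount of 1, 16 at 1.5-fold (4 higher, 12 lower) and 0 at 3 times the minimum, where 18 are tested; no repeat family is left at 3 times the minimum for H3K27me3. The correlation of repeat RNA and H3K9me3 (-0.04) was 0.036 with male effects only, 0 with female effects only, 0.214 with a pseudocount of 0.1 and -0.381 with the low filter. Gene lists that passed (8 in males, 3 in females, 7 over both) were 2, 0 and 0 with an estimated correlation and 3, 0 and 2 by fry.

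Leaving out 1 library at a time, where a lone KO library is assumed to vary like the other groups, gave 29 to 88 genes in males, 3 to 164 in females, 53 to 256 over both sexes, 1 to 10 for the difference between the sexes, 3218 to 4375 for female against male and 0 to 3 for Het1 against Het2. Repeat families ranged from 3 to 5, 2 to 5, 5 to 6 and, for the difference between the sexes, 0 to 2. The low ends were without male KO replicate 1 (29 and 53), male KO replicate 2 (36 and 57), female KO replicate 1 (3 and 65) or female KO replicate 2 (5 and 83), and 164 and 256 came without female Het2 replicate 1.

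Values that reversed were small or came from few libraries, and none of the genes among them passed in the reported fit. For female against male, Sycp2 was -0.056 and Tdrd9 -0.235 with Het1, Kit -0.134 with Het2 and Sall4 -0.37 to 0.042 leaving out 1 library, positive without female Het2 replicate 1. Over both sexes, Figla was -0.199 with a pseudocount of 0.1, -0.046 with Het2 and -0.236 to 0.612 leaving out 1 library, Amh -0.076 with Het1 and -0.301 to 0.851 leaving out 1 (-0.031 without male Het2 replicate 1), Cdh5 -0.012 by quantile normalization, and Hba-a2 -0.074 with Het2 and -0.431 to 1.324 leaving out 1. Leaving out 1 library gave Nanos2 -0.045 to 1.268, C1qb -0.258 to 1.016, C1qa -0.083 to 0.728, Csf1r -0.401 to 0.103, Hbb-b1 -0.482 to 1.958, Hbb-y -0.226 to 1.676 and Hba-a1 -0.494 to 1.354. Without male KO replicate 1, C1qa was -0.041, Hbb-b1 -0.051, Hba-a2 -0.243 and Hba-a1 -0.218. In females AluG_3 was 0.021 with Het2 and -0.119 to 0.033 leaving out 1 library, and PB1D9 0.015 with Het2 and -0.132 to 0.056 (0.05 without female KO replicate 1). Over both sexes MMETn-int was -0.389 by quantile normalization and -0.01 (without male KO replicate 2) to 1.066 leaving out 1, MMVL30-int -0.169 by median centring and -0.426 by quantile normalization, and RLTR4_Mm, which had passed, -0.012 by median centring. PB1 was -0.319 by median centring, -0.454 by quantile normalization, -0.005 (without female KO replicate 2) to 0.109 leaving out 1, and -0.086 with the low filter and centring; PB1D9 was -0.358, -0.52, -0.032 to 0.062 and -0.165, and also -0.016 with Het1 and -0.008 with wild type added. With the low filter and centring MERVL_2A-int was -0.016, MT2B2 -0.054, B4 -0.03, B4A -0.037 and ID4_ -0.096. RNA depth is unknown, so its limit is not given; with 1 read at 0.017 to 0.025 RPKM, promoter marks near 0.1 RPKM rest on a few reads.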

Other observations

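Each test in this part was chosen after the results were seen.

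A hypothesis was that the promoters of the 137 genes raised over both sexes carry H3K9me3 in control germ cells. Their median in Het was 0.233 RPKM against 0.188 in random lists matched on expression (99.72nd percentile). The matching used the mean over Het and KO libraries, so genes raised in KO tended to be set beside genes with higher expression in Het. This alone could raise the percentile, so no conclusion on a mark present before the loss is drawn from it. The levels are low, and the change in KO, a median of -0.11 against -0.07, lay at the 18.28th percentile. A further hypothesis was that these promoters lose H3K27me3. The median change was -0.27 against -0.12, below all 10000 matched lists (percentile 0), while the levels in Het were alike (0.454 against 0.422 RPKM, 75.04th percentile). The matching was the same, with its limit. D1Pas1 (log2 differences -0.74 and -1.28; RNA 1.80) and the fibrillin gene Fbn2 (-0.73 and -0.93; RNA 0.78) are examples past 1.5-fold in both sexes, picked after their values were seen. Such a loss may follow transcription rather than precede it, which these data do not order.

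At a 1.5-fold limit H3K27me3 was also lower at the promoters of H2-T24, Lmna, Hmga2, Igfbp5 and Erbb2, and higher at those of the germ cell regulators Prdm14 (0.434 to 1.03 RPKM in males and 0.669 to 1.12 in females) and Sall4 (0.417 to 1.17 and 0.61 to 1.003) and of Tdgf1. RNA of Prdm14 (-0.27, adjusted p = 0.789 by limma), Sall4 (-0.42, 0.418) and Tdgf1 (0.20, 0.704) did not pass.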
